A study of Caenorhabditis elegans with 2 samples.

How the data were processed

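Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans larvae carrying a transgene in which F26F4.8 was fused to EGFP, with TY1 and 3xFLAG tags. Per the labels, the animals were fourth-stage (L4) larvae of 48 hours grown from starved first-stage larvae, the fusion protein was precipitated with an anti-GFP antibody and chromatin was sheared by sonication. There was 1 group of 2 biological replicates, numbered as the labels number them. No untreated, untagged or mock precipitation was used here, so no contrast between groups was made.

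The authors' deposited files were peak lists on the ce11 build. The file records deposited with the samples list, beside the alignments of the replicates, an input shared by every ranked list and by the tracks of fold change over control, which was taken to be the control. The peak caller, the aligner and the number of reads are not given in the sources used here, so the depth of each library was unknown and no depth-based limit was set. Each of 4 ranked lists held every peak matched between a pair of peak lists by the irreproducible discovery rate (IDR), the expected share of calls that would not repeat. There was 1 ranked list per replicate and 2 lists of peaks called on pooled reads. The list that paired the replicates was the source of the conservative set. Its 2 columns of per-replicate signal are not named. They were matched to the replicates by value: at 958 of the 978 conservative peaks the first held the signal of an overlapping peak in the list of replicate 1, at 973 the second held that of replicate 2, and at 0 was it the other way round. Signal agreement used these columns.

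The authors' deposited signal value is the peak caller's measure of enrichment per peak against the control, in arbitrary units, with no scaling between lists stated. It was used only to describe and rank peaks within a list. Per the labels of the output types and from the values, the deposited −log10 values are those of the local and global IDR, capped at 5 in the ranked lists; the −log10 q-values of the caller were not used. The deposited score, a whole number up to 1000, was found to follow the log of the global IDR, within 1 unit for 109986 of the 109990 peaks of the cross-replicate list. The lowest score in the conservative set was 830, and the highest global IDR in it was 0.00999, so the authors' lists stopped at an IDR of 0.01. Each thresholded list also left out some peaks past that threshold. The file records list a further input file for this step without stating what it holds.

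What was computed here started from those lists. Peaks in the conservative set are called listed peaks, and they were compared with the other peaks of the ranked list they came from. The alternatives used the other thresholded pooled set, or the thresholded list of a single replicate against its own ranked list, which is what leaving out the other replicate gave. A summit was near a transcription start site (TSS) when it lay within 500 bp of the 5′ end of an annotated protein-coding transcript, and near an RNA gene when it lay within 200 bp of the gene. Genes came from Ensembl release 115 on WBcel235, whose chromosome names and lengths matched ce11, and tRNA isotypes and pseudogenic tRNA genes came from the RefSeq annotation of the same assembly. Coordinates are 1-based. Gene names shared by several genes were replaced by sequence names. U6 genes were recognised among small nuclear RNA genes by a conserved core sequence of U6 RNA, without mismatches.

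Shares were tested with two-sided Fisher's exact tests and given with 95% Wilson intervals. Values printed as log10 p are one-sided and not adjusted. Benjamini-Hochberg adjustment was made over the 6 chromosomes, the 8 classes of RNA gene, the 30 gene lists or the 2080 6-mers of a test. Gene lists were tested among the 14963 protein-coding genes with any ranked peak within 500 bp of a TSS. The lists covered ribosomal proteins, translation factors, tRNA synthetases, the proteasome, the respiratory chain, histones, major sperm proteins, collagens, heat shock proteins, nuclear hormone receptors, homeobox genes, cytochromes P450, UDP-glucuronosyltransferases, glutathione transferases, C-type lectins, chemoreceptors, F-box A and B genes, BTB and MATH genes, Skp1-related and cullin genes, DREAM and synMuv B genes, cell cycle genes, dosage compensation genes, RNA interference genes, splicing factors, and markers of germline, intestine, body muscle, pharynx, hypodermis and neurons. 6-mers within 50 bp of summits were tested against 2 flanks per peak of the same length, starting 250 bp away. Replicates' lists were compared by overlap of at least 1 bp. Signal agreement was measured with Spearman's rho and Pearson's r of log2 values, each with 100000 permutations. The agreement of identical tRNA gene copies was measured on log2 signals from each replicate's own ranked list, for genes with no other tRNA gene within 400 bp, with 10000 resamplings of sequences. The highest signal within 20 kb of a gene was ranked among windows of that size on its chromosome.

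Peaks are not replicates, and neighbouring peaks or genes are not independent. The p-values compare peaks within these lists, and the intervals cover counting error only.

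Genes were named by a rule fixed before the data were examined. Each listed peak was assigned to the nearest protein-coding TSS. The rule took the 20 strongest peaks; up to 4 members with the highest signal of each list past the threshold or with at least 3 members carrying a peak; F26F4.8 and unc-119; up to 3 genes of each RNA class past the threshold; and up to 3 strongest peaks of each replicate absent from the other replicate's ranked list. The design, the gene lists and most alternative settings were also set before the data were examined. A stricter IDR of 0.01, set then, equalled the authors' own threshold and changed nothing, so 0.001 was added later.

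The list, class, chromosome, TSS, centre and 6-mer tests were tested on simulated data. There were 20 random draws, of the size of the conservative set, from the ranked peaks outside it. Except in the 6-mer test, the listed peaks stayed in the comparison group. Random draws also do not cluster as neighbouring listed peaks do. The calls with nothing planted therefore do not give the rate of false calls in the real lists. With 10 peaks planted at ribosomal protein TSSs, the gene list test called that list in 20 of 20 draws; with nothing planted it made 0 calls. With 20 peaks planted at snoRNA genes the class test called that class in 20 of 20 draws, and with nothing planted it made 2 calls over 160 class tests. A 6-mer planted in 10% of windows was called in 20 of 20 draws, and windows dealt at random gave 0 calls. That deal mixed summits with flanks, so it does not show how many 6-mers are called between summits and flanks with nothing planted. With nothing planted, the chromosome test made 1 call in 120 tests, the TSS test passed in 2 of 20 draws and the centre test in 1 of 20. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.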

Results

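F26F4.8 encodes a protein annotated as containing a C2H2-type zinc finger domain, and the experiment mapped where its EGFP fusion was recovered on the genome of L4 larvae. Both biological replicates had their own ranked and thresholded peak lists, and the pooled reads gave a conservative set of peaks called across replicates. The conservative set held 978 peaks with a median pooled signal of 87.9 in the caller's arbitrary units, out of 109990 ranked peaks with a median of 23.8. Most peaks had the same width, with a median of 264 bp. Replicate 1 alone gave 376 thresholded peaks out of 64220, and replicate 2 gave 366 out of 59972. The pooled lists were made from the reads of both replicates, so their greater length is not an independent count.

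Genes for tRNAs, small nucleolar RNAs (snoRNAs) and small nuclear RNAs were far more frequent at listed peaks than at other ranked peaks, although 526 listed peaks (53.8%) had no tRNA, pseudogenic tRNA, snoRNA, small nuclear RNA, rRNA, microRNA, ncRNA or long intergenic RNA gene within 200 bp. Of the 978 listed peaks, 332 (33.9%; 95% Wilson interval 31.0 to 37.0) had a tRNA gene within 200 bp of the summit, against 0.185% of the other ranked peaks. The snoRNA genes, whose RNAs guide the modification of other RNAs, lay beside 47 peaks (4.81%; 3.63 to 6.33), against 0.224% of the others. Small nuclear RNA genes lay beside 14 peaks (1.43%; 0.855 to 2.39), against 0.0807%. In all, 360 of the 612 nuclear tRNA genes (58.8%; 54.9 to 62.7) had a listed peak within 200 bp, as did 48 of 346 snoRNA genes (13.9%; 10.6 to 17.9) and 14 of 129 small nuclear RNA genes (10.9%; 6.58 to 17.4).

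The odds of a tRNA gene lying near the summit were 277 times higher for listed than for other ranked peaks. The log10 p of the one-sided Fisher's exact test, not adjusted, was -557. The odds ratio was 22.5 for snoRNA genes (adjusted exact p = 2.21e-43 over the 8 classes) and 18 for small nuclear RNA genes (adjusted exact p = 1.02e-12). The heterogeneous class annotated as ncRNA lay beside 287 peaks (29.3%, against 4.06%; odds ratio 9.82, adjusted exact p = 2.26e-153). These genes overlapped the other classes, and only 48 of the listed peaks had an ncRNA gene but no tRNA, snoRNA, small nuclear RNA or microRNA gene nearby. MicroRNA genes lay beside 5 peaks (odds ratio 3.50, adjusted exact p = 0.0264), a call that did not hold in the other thresholded set (adjusted exact p = 0.0814) nor in replicate 1 (adjusted exact p = 0.208) or replicate 2 alone (adjusted exact p = 0.156). Genes for piRNAs (adjusted exact p = 1) and long intergenic RNAs (adjusted exact p = 1) did not pass, with 8 and 3 peaks. No listed peak lay beside an rRNA gene, which with 978 peaks gives an upper Wilson bound of 0.391%. Most of the 20 nuclear rRNA genes had no ranked peak either, so they could not have had a listed one, and the bound does not show absence there. With the peaks past the IDR threshold that the authors left out put back, 2 of 1110 did, at the 5S rRNA genes ZK218.20 and Y102A5D.10, and the class passed (odds ratio 39.3, adjusted exact p = 0.00331). Of the nuclear tRNA genes with a single-copy sequence 38.6% had a listed peak, and of those with identical copies 64.8%.

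Genes for tRNAs and snoRNAs were enriched in each replicate on its own. A tRNA gene lay near 48.4% of the 376 peaks of replicate 1 (43.4 to 53.4) and 51.6% of the 366 peaks of replicate 2 (46.5 to 56.7). The shares for snoRNA genes were 10.4% (7.68 to 13.9) and 11.5% (8.60 to 15.1). At an IDR of 0.001 the shares among the 237 peaks left were 52.3% for tRNA, 16% for snoRNA and 46% for ncRNA genes. With summits required to lie inside the gene, snoRNA genes fell to 3 peaks (0.307%; odds ratio 6.57, adjusted exact p = 0.0248) and small nuclear RNA genes to 9 (0.920%). By gene, 204 tRNA genes carried a peak in the thresholded list of replicate 1 and 208 in that of replicate 2. For small nuclear RNA genes the numbers were 8 and 5, and the odds ratios of the class were 22.4 and 10.3.

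**Figure D1:**
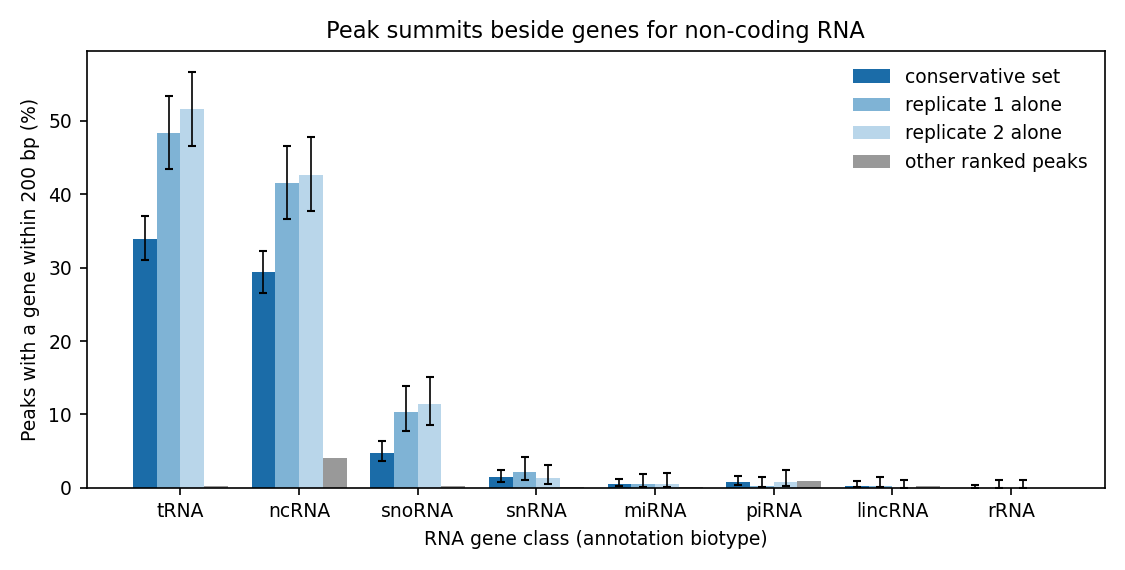
Share of peaks (%, vertical axis) whose summit lay within 200 bp of a gene of each non-coding RNA class (horizontal axis), for the conservative set, each replicate's own thresholded list and the other peaks of the cross-replicate ranked list. Error bars are 95% Wilson intervals; tRNA genes lay beside 33.9% of the conservative peaks and 0.185% of the other ranked peaks.

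Summits sat inside tRNA genes and just upstream of snoRNA genes. For tRNA genes the summit lay inside the gene for 249 of 332 peaks (75%), with a median position 22.5 bp from the gene's 5′ end (quartiles 8 and 42 bp). The median length of the nuclear tRNA genes was 72 bp. At snoRNA genes 40 of 47 summits lay upstream of the gene, at a median of 32 bp before its 5′ end, 3 lay inside it and 4 lay downstream. Peaks at snoRNA genes away from tRNA genes had a higher median signal (190, n = 44) than peaks at tRNA genes (109, n = 332), a ratio of 1.73 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give).

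**Figure D2:**
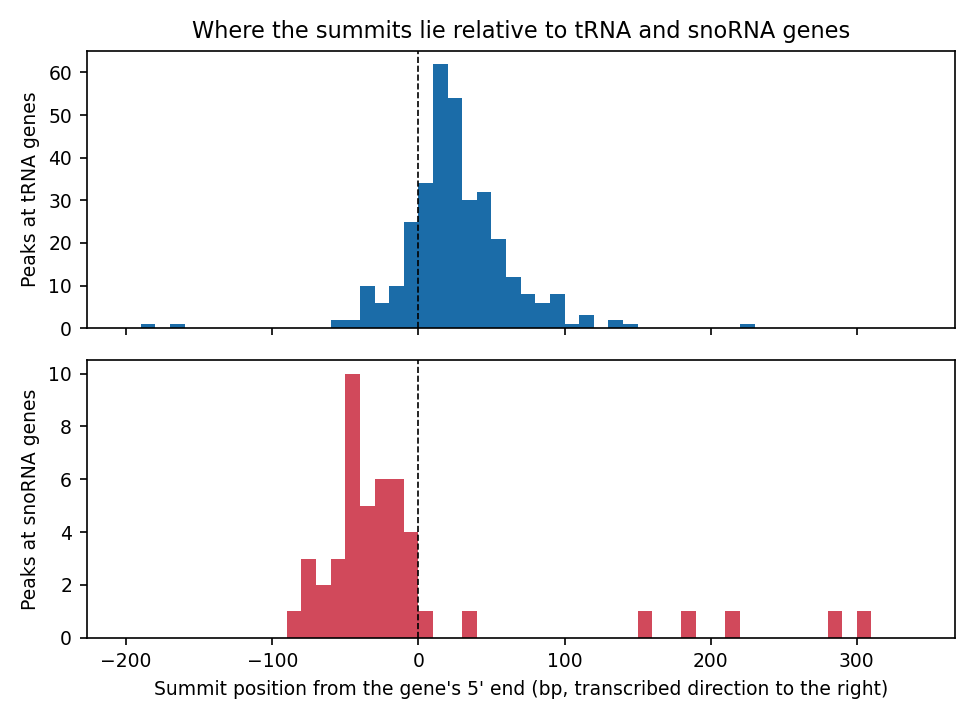
Number of listed peaks (vertical axes) by the position of the summit relative to the 5′ end of the nearest tRNA gene (upper panel) or snoRNA gene (lower panel) within 200 bp, in bp with the direction of transcription to the right (horizontal axis). The dashed line marks the 5′ end; 249 of 332 summits lay inside the tRNA gene and 40 of 47 lay upstream of the snoRNA gene.

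The strongest peaks were mostly at snoRNA genes. Among the 20 listed peaks with the highest signal, 12 had a snoRNA gene within 200 bp, 4 a tRNA gene and 1 a U6 gene, and 13 of the summits lay in an intron of a protein-coding gene. The remaining 7 were intergenic and none lay in an exon or a UTR. The highest signal, 488 (296 in replicate 1 and 180 in replicate 2), was at chromosome V 8500451 to 8500670, in an intron of pxn-1, which encodes a peroxidasin, beside the snoRNA gene ZK994.7. A peak on V at 12303551 to 12303731 (signal 423; 221 and 200) lay in an intron of frm-7 at the snoRNA genes C51F7.4 and C51F7.3, and its nearest TSS was that of F55C5.17. On chromosome II at 11960732 to 11960901 a peak of signal 350 lay in the intergenic region nearest W03C9.1, beside the snoRNA gene W03C9.9. A peak on I at 13463870 to 13464053 (signal 332; 193 and 141) lay in an intron of ints-8 at rpr-1, the gene for the RNA component of RNase P, the enzyme that trims tRNA precursors. The strongest tRNA peaks were those at the leucine tRNA gene C04A11.t1 (X, 13665532 to 13665653, signal 286; nearest TSS C04A11.5) and at the alanine tRNA genes F15G9.t1 and F15G9.t2 in an intron of him-4 (X, 9743564 to 9743679, signal 286; nearest TSS F15G9.5). Of the rest, peaks nearest the TSSs of cutl-18, sre-23, Y23H5B.5, pamn-1, Y75B12B.11, twk-5, Y43F8C.7, unc-41 and str-56 lay beside snoRNA genes. Those nearest mog-3 and egl-17, which encodes a fibroblast growth factor, lay beside tRNA genes. The peaks assigned to ccm-2 (IV, 1831354 to 1831449, signal 351, in an intron of cmk-1) and eif-3.G (II, 8441631 to 8441786, signal 270, in an intron of lips-10) had no annotated RNA gene within 200 bp.

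Among small nuclear RNA genes the highest signals were all at U6 genes, whose RNA is part of the spliceosome. They were W05B2.8 (III, 10989679 to 10989780, signal 270, in an intron of dhc-4, nearest TSS col-94), F54D8.7 (III, 5080798 to 5080898, signal 175, intergenic) and Y9C9A.111 (IV, 4930954 to 4931055, signal 162, in an intron of Y9C9A.8). In the ncRNA class the highest signals were at T03F7.14 (344), rpr-1 (332) and Y23H5B.13 (317), of which the first and the last also lay at snoRNA genes. The microRNA genes with the highest signals were mir-51 (162; IV, 11026013 to 11026112), mir-4936 (133) and mir-2214 (83.1).

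The sequences at the summits held the internal promoter elements of tRNA genes, the A box and the B box, at which RNA polymerase III is recruited through the factor TFIIIC. Of 2080 6-mers, 638 were more frequent within 50 bp of listed summits than in the flanks and 416 were less frequent. The leading one, CGAACC with its reverse complement GGTTCG, occurred at 23.2% of 978 summits and in 3.94% of 1956 flanks (odds ratio 7.38, adjusted exact p = 1.14e-51). ACCACT, or AGTGGT, occurred at 21.4% against 3.22% (odds ratio 8.17, adjusted exact p = 5.30e-51). GGTTCG is part of the B box consensus GGTTCGANNCC, and GAGTGG, found at 10.8% of summits against 1.53%, is compatible with the A box consensus TRGCNNAGTGG. The 6-mers lost most at summits were A- and T-rich, led by AAAAAT (19.3% against 45.6%). When ranked peaks at tRNA genes were left out, 443 6-mers were still enriched, among them 9 of the 10 that led before. TGGCCG then led, at 11.3% of 646 summits against 1.78% of flanks (odds ratio 7.03, adjusted exact p = 2.55e-16). CGAACC was no longer among the leading 6-mers, and ACCACT fell to 11.5% of summits, against 2.94% of flanks. G- and C-rich 6-mers such as CGCGCC (7.74% against 0.774%) were among the leaders, and AAAAAT stayed rarer at summits (19.5% against 46.7%). Summits and flanks thus also differed in base composition.

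Whole boxes were searched for with at most 1 mismatch within 100 bp of each summit, a search chosen after the 6-mers had been seen. An A or B box lay at 95.2% of the listed peaks at tRNA genes, against 10.2% of their flanks. The boxes are internal elements of tRNA genes, so this share followed from the choice of peaks and says nothing further about binding. At the 44 listed peaks at snoRNA genes away from tRNA genes the share was 81.8%, against 4.55% of their flanks. The flanks were not matched to the summits in base composition. At the frm-7 peak the B box match was GGTTCGACCCC (V, 12303663 to 12303673), and the same sequence lay beside W03C9.9 (II, 11960870 to 11960880). Near the summit at C04A11.t1 lay the A box match TGGCCGAGTGG (X, 13665562 to 13665572) and the B box match GGTTCGAATCC (X, 13665652 to 13665662), the latter mostly beyond the end of the peak. Of the peaks without an annotated RNA gene, that in cmk-1 held neither box and that in lips-10 held an A box match, TGGCTTAGTGG (II, 8441687 to 8441697). Of the 20 strongest peaks, 16 had at least 1 of the boxes and 5 had both.

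Protein-coding promoters were not preferred. A protein-coding TSS lay within 500 bp of 247 listed summits (25.26%; 22.6 to 28.1), against 24.1% of the other ranked peaks (odds ratio 1.07, exact p = 0.388), and 69 of the 247 were also at tRNA genes. Within 200 bp of a TSS the share was lower than among the other peaks, 8.79% against 10.8% (exact p = 0.0387). Without peaks at tRNA genes it was 27.6%, against 24.1% (exact p = 0.0424). Counting the start sites of all annotated genes, RNA genes included, it rose to 62.2% against 32.6% (exact p = 9.48e-79).

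Of the 30 gene lists, 1 passed the threshold. Histone genes, which encode the proteins that package DNA, had a peak at the TSS in 7 of the 43 tested members (16.3%; 8.12 to 29.97), against 1.61% of other genes (odds ratio 11.9, adjusted exact p = 0.000179). The 7 genes rested on 6 peaks. his-61 and his-62 shared a peak on IV at 7485939 to 7486202 (signal 105; 58.3 in replicate 1 and 48.4 in replicate 2), close to those of his-60 (102) and his-59 (75.9), and his-64 (IV, 11407404 to 11407667) had a signal of 93.8. The other members were H02I12.6 (73.4; summit at IV, 11400287), in the neighbourhood of his-64, and his-67 on I (59.9). The test and its interval treated such neighbouring genes as independent. None of these peaks had an annotated RNA gene within 200 bp. The list passed in replicate 1 alone, with 5 of 37 tested members (adjusted exact p = 0.000359), and did not in replicate 2 alone, with 2 of 37 (adjusted exact p = 0.974). Within 1000 bp of the TSS 14 of 55 had a peak (25.5%, adjusted exact p = 6.96e-09). Within 200 bp the list did not pass (1 of 28, adjusted exact p = 1), and at an IDR of 0.001 no histone gene was left among the 56 genes with a peak.

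The other lists did not pass the threshold within 500 bp, and within 1000 bp ribosomal proteins (10.3%, adjusted exact p = 0.0151) and collagens (8.02%, adjusted exact p = 0.00982) did. Ribosomal protein genes had 4 of 70 members with a peak (5.71%, adjusted exact p = 0.318), namely rpl-3 (signal 142), rpl-15 (114), rps-15 (65.5) and rpl-43 (60.1). Heat shock proteins had 3 of 42 (adjusted exact p = 0.318), which were the chaperone genes dnj-28 (83.6), hsp-6 (69.9) and hsp-110 (61.9). Collagens had 5 of 145 (adjusted exact p = 0.554), with the highest signals at col-85 (171) and col-54 (131), both beside a tRNA gene, and at col-87 (90.4) and col-73 (74.6). Homeobox genes had 3 of 73 (adjusted exact p = 0.599), namely ceh-43 (97.2), which lay at an arginine tRNA gene, vab-3 (78.2) and ceh-12 (60.4). Chemoreceptor genes had 8 of 757 (1.06%, adjusted exact p = 0.948), led by srh-269 (151, at a glutamine tRNA gene), srh-220 (90.0), srh-214 (84.9) and srh-36 (79.6). There were 2 members with a peak among each of the nuclear hormone receptors, F-box A and B genes, splicing factors (adjusted exact p = 0.948 for each) and pharynx markers (adjusted exact p = 0.410). There was 1 member each among tRNA synthetases, major sperm proteins, cytochromes P450, glutathione transferases, C-type lectins, BTB and MATH genes, and markers of germline, body muscle, hypodermis and neurons, with adjusted p-values from 0.948 to 1. Translation factors, the proteasome, the respiratory chain, UDP-glucuronosyltransferases, Skp1-related and cullin genes, DREAM and synMuv B genes, cell cycle genes, dosage compensation genes, RNA interference genes and intestine markers had 0 members with a peak, and the adjusted p was 1 for each.

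Listed peaks were spread over all 6 chromosomes. The X chromosome held 214 of the 978 listed peaks (21.9%; 19.4 to 24.6), against 17.4% of the other ranked peaks (odds ratio 1.33, adjusted exact p = 0.00222 over 6 chromosomes). It held 26.9% in replicate 1 alone (odds ratio 1.82) and 28.4% in replicate 2 alone (odds ratio 2.02). Chromosome V held fewer, 16.3% against 20.3% (odds ratio 0.764, adjusted exact p = 0.00538). The shares on I, II, III and IV were 15.7%, 14.3%, 16.4% and 15.4%, with adjusted p-values from 0.0861 for II to 1 for I. Chromosome II held fewer in the other thresholded set (13.9%, adjusted exact p = 0.0269) and in replicate 2 alone (9.84%, adjusted exact p = 0.00072). Without the peaks at tRNA genes the difference on X turned round, to 9.91% against 17.4% (odds ratio 0.524, adjusted exact p = 7.28e-07), and that on V did not pass the threshold (adjusted exact p = 0.485). On the autosomes, 47.9% of listed and 46.5% of other ranked peaks lay in the middle 50% of the chromosome (exact p = 0.444). In the replicates' own lists the share in the middle was higher than among the other peaks, at 54.9% against 46% in replicate 1 (exact p = 0.00353) and 55.7% against 46.2% in replicate 2 (exact p = 0.00228).

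The replicates overlapped well beyond their ranked background. Of the 376 thresholded peaks of replicate 1, 236 (62.8%; 57.8 to 67.5) overlapped a thresholded peak of replicate 2, against 0.205% of its other ranked peaks (odds ratio 820, one-sided Fisher's exact log10 p of -467). In the other direction 240 of 366 peaks (65.6%; 60.6 to 70.3) overlapped, against 0.232% (odds ratio 821, one-sided Fisher's exact log10 p of -471). In the conservative set 342 of the peaks of replicate 1 (91.0%; 87.6 to 93.5) and 331 of replicate 2 (90.4%; 87 to 93) had a counterpart. Across the 978 listed peaks the signal values of replicates 1 and 2 had a Spearman rho of 0.567 and a Pearson r of 0.728 on log2 values (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These are correlations across peaks chosen for passing in both replicates, and over all 109990 ranked peaks rho was 0.275. The signal was 1.13-fold higher in replicate 1 at the median peak, with no scaling between the replicates stated.

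**Figure D3:**
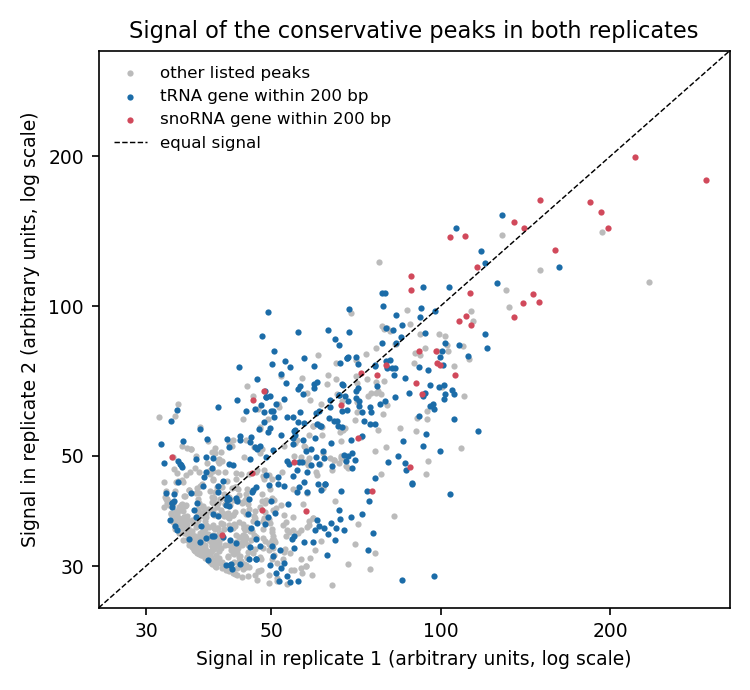
Signal of each of the 978 listed peaks in replicate 1 (horizontal axis) and replicate 2 (vertical axis), in the caller's arbitrary units on log scales. Peaks at tRNA and snoRNA genes are coloured and the dashed line marks equal signal; rho across the peaks was 0.567.

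Few peaks were private to a replicate. In replicate 1, 9 of 376 thresholded peaks overlapped no ranked peak of replicate 2, and the strongest lay in an intron of tpra-1 (IV, 8964122 to 8964377, signal 97), in a coding exon of ZK154.1 (X, 57.7) and in the intergenic region nearest Y48C3A.5 (II, 55.8). None of the 3 had an annotated RNA gene nearby. In replicate 2 the number was 10 of 366. The strongest lay at the lysine tRNA gene W03G11.t1 (X, 12106110 to 12106353, signal 91.5, nearest TSS col-181), the glycine tRNA gene Y57G11B.t1 (IV, 85.4, nearest TSS Y57G11B.5) and the glutamate tRNA gene ZK622.t2 (II, 65.7, nearest TSS ZK622.1).

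Around the tagged gene itself the listed peaks were crowded. F26F4.8 lies on III at 4903997 to 4905473, and no listed peak lay within 500 bp of the gene, where the highest ranked signal was 70.1. Within 20 kb of it there were 9 listed peaks, against a mean of 0.390 per window of that size over the genome and at most 6 in any window away from the gene. Their signals ran from 83.1 to 120, and none lay at a tRNA, snoRNA or small nuclear RNA gene, while the strongest had the ncRNA gene F26F4.14 nearby. The 9 included summits in coding exons of nhl-2, tag-340, rom-1, rars-1, mmab-1 and set-2. The highest signal near the gene ranked 35th of 345 windows on the chromosome, at the 89.9th percentile. Both replicates alone gave the 90.7th percentile, with 4 listed peaks in the window in replicate 1 and 6 in replicate 2. At unc-119 (III, 10902641 to 10908935), whose functional copy was carried by the same transgene in a mutant background, there was no listed peak within 20 kb, and the highest ranked signal of 48.4 was at the 6.38th percentile. In the lists of replicates 1 and 2 alone, also without a listed peak there, it was at the 60th and the 60.6th percentile.

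**Figure D4:**
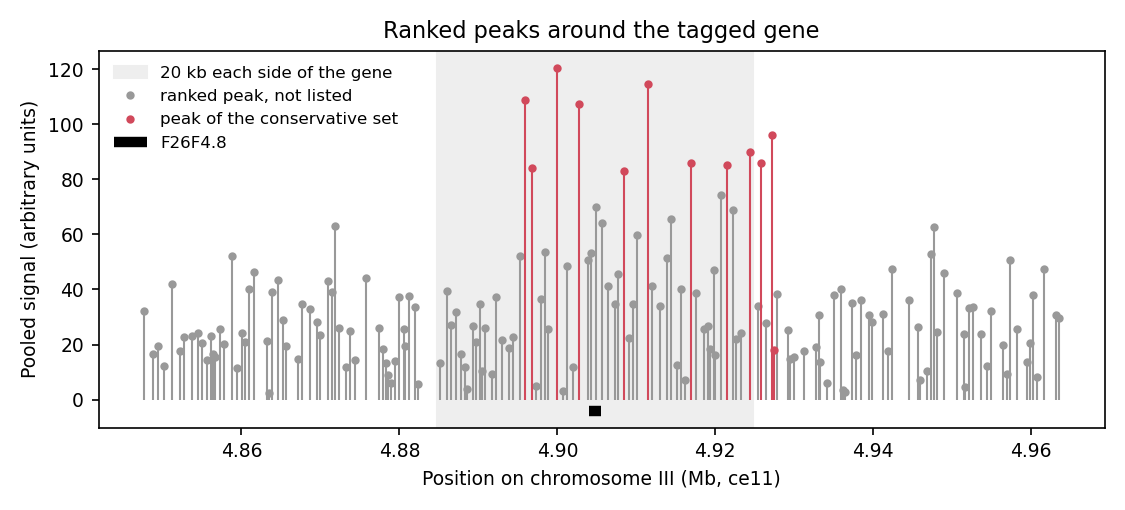
Pooled signal (vertical axis, arbitrary units) of every ranked peak within 60 kb of F26F4.8 by its position on chromosome III (horizontal axis, Mb on ce11), with listed peaks in red, other ranked peaks in grey, the gene as a black bar and 20 kb on each side shaded. The 12 listed peaks in view lay between 4895919 and 4927405.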

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

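The single-copy test of tRNA genes, the box search in the missing peaks and the search for repeated sequence were set before their results were seen. The tests of ribosomal protein and other gene lists, promoters, differing gene copies, missing peaks at RNA genes and the surroundings of F26F4.8 and unc-119 were chosen after the result was seen.

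In the cross-replicate ranked list 132 peaks passed the IDR threshold and were left out of the conservative set, and the highest pooled signal among them was 4542 (X, 15810947 to 15811198, intergenic), against 488 for the strongest listed peak. The missing peaks may be repeated sequence, since most 30-base stretches within 100 bp of the summit occurred elsewhere in the genome in 91.7% of missing and 13.2% of listed peaks (Fisher's exact test, p = 1.42e-76). The box search set beforehand decided nothing about whether they were the same kind of site: 8.33% had an A or B box (4.72 to 14.3), against 26% of listed peaks away from tRNA genes, and the interval reached past 0.5 of that share. A later count argued against it for the missing peaks as a set, as 0% (0 of 132; upper Wilson bound 2.83%) lay at a tRNA, pseudogenic tRNA, snoRNA or small nuclear RNA gene, against 40.6% of listed peaks, although 2 lay at 5S rRNA genes, where no listed peak lay. What removed them is not given in the sources used here.

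For the peaks at tRNA genes, strong transcription of any kind was considered as the whole cause, through protein-coding genes taken to be strongly transcribed. At the TSS 5.71% of ribosomal protein genes (upper bound 13.8%) and no translation factor gene (upper bound 9.18%) had a peak, against 58.8% of tRNA genes. Histone genes, at 16.3%, had an upper bound of 29.97%, just above 0.5 of the tRNA share. These genes thus had a peak at the TSS less often than tRNA genes had one. Expression was not measured, and the shares were counted differently. For tRNA genes the whole gene with 200 bp on each side counted, and for the others only 500 bp around a TSS. The comparison therefore cannot decide, and transcription as the whole or a part of the cause stays open. The ribosomal protein share was above the 1.63% of other genes (Fisher's exact test, adjusted p = 0.318). Within 1000 bp of the TSS the histone, ribosomal protein and collagen lists passed. The strongest collagen peaks, at col-85 and col-54, lay beside tRNA genes. The lists at 1000 bp were not tested without peaks at tRNA genes, so the collagen call cannot be ascribed to transcription of collagens. Protein-coding promoters in general were at most weakly preferred. The odds ratio near their TSSs was 1.07 (0.922 to 1.23), and 1.20 (1.01 to 1.42) without peaks at tRNA genes. Open chromatin at the tRNA genes themselves was not measured, so this promoter test cannot decide on it. Reads shared between gene copies stay open as a part of the cause: 38.6% of single-copy genes had a peak (30.9 to 46.8), against 64.8% of genes with copies, and of only 20 genes without a shared 30-base stretch 2 had a peak (2.79% to 30.1%). Of the 332 peaks at tRNA genes 7 (2.11%) were mostly repeated sequence, but a tRNA gene, of 72 bp at the median, fills only a part of a peak. Even sharing as the whole cause was tested after these. A count of copies with and without a peak, made before that test, could hardly have come out otherwise. Copies of the same sequence differed in the same way in both replicates. Their deviations from the mean of their copies had a correlation of 0.638 (bootstrap interval over sequences 0.564 to 0.710), against 0.656 across the same 284 genes. The test cannot decide, since the sequence beside each copy and the input taken as control were the same in both replicates. Either could make copies differ alike under even sharing, which stays open. Recovery of tRNA genes in any precipitation, with or without the tagged protein, stays open as untested, since no untagged control was analysed here, and the promoter test was put in place of it.

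Whether the crowding of listed peaks around F26F4.8 comes from extra copies of the genomic fragment carried by the transgene cannot be told apart from binding there. Unlisted peaks were raised around the gene, with a median signal of 29.5 against 24.0 over the chromosome, at the 95.4th percentile of 345 windows, which narrowly passed a limit of 95 set after medians nearby had been looked at. Around unc-119, which the same transgene carries, they were not (median 22.5, 26.4th percentile). The labels do not say how much sequence around unc-119 was carried. The 12 listed peaks within 60 kb of F26F4.8 all lay between 4895919 and 4927405, a span of 31.5 kb. The window used for the median around F26F4.8 ran from 4884735 to 4924735. That median therefore mixed unlisted peaks inside and outside the span, and may understate how far those inside were raised. Whether the span matches the carried fragment was not tested. The presence of RNA genes does not account for the crowding: 0% of the 9 peaks lay at a tRNA, pseudogenic tRNA, snoRNA or small nuclear RNA gene (upper bound 29.9%), and away from such genes no other window of that size held more than 6. Binding of the protein at its own locus stays open, as untested.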

How the results depend on the processing

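Alternatives at an IDR of 0.001, with the removed peaks put back, with neighbouring peaks counted once, without peaks at tRNA genes or without peaks weaker in the pool than in both replicates were chosen after seeing the data; the others were set before. Of the alternative values, 458 changed no call or, where nothing was tested, stayed near their value, while 10 lost a call, 12 gained a call, 2 turned a called direction round and 17 without a test moved further; values without a call could change direction, and some with a call moved far, such as rho between replicates, 0.275 over all ranked peaks. The stricter IDR of 0.01 set before equalled the authors' own threshold, so it gave no separate value. Leaving out a replicate gave 366 to 376 peaks, 81 to 89 genes with a peak at the TSS, 399 to 423 enriched 6-mers, 54.9% to 55.7% of peaks in chromosome centres, 60th to 60.6th percentiles at unc-119, 9.84% to 13.8% of peaks on II, 0.532% to 0.546% of peaks at microRNA genes and 5.41% to 13.5% of histone genes with a peak. At an IDR of 0.001 there were 237 peaks, 56 genes, 338 6-mers, 14.8% of peaks on V (adjusted exact p = 0.106), 0.844% at microRNA, 52.3% at tRNA, 16% at snoRNA and 46% at ncRNA genes and 0% of histone genes, with fewer peaks to test. Without peaks at tRNA genes 27.6% of summits were near a TSS (exact p = 0.0424), and X and V held 9.91% and 18.9%. Overlap of 50% of both lengths gave 85.6% and 83.3% of the peaks of replicates 1 and 2 in the conservative set. TSS windows of 200 and 1000 bp gave 83 and 472 genes. At 200 bp 8.79% of summits were near a TSS and 3.57% of histone genes had a peak; at 1000 bp 25.5% of histone genes had a peak, and ribosomal protein genes (10.3%, adjusted exact p = 0.0151) and collagens (8.02%, adjusted exact p = 0.00982) passed. All annotated genes gave 62.2% near a TSS, and a narrower middle of the autosomes held 33% (exact p = 0.0467). The other thresholded set gave 13.9% on II and 0.417% at microRNA genes, and putting removed peaks back gave 14.1% on II and 0.180% at rRNA genes (adjusted exact p = 0.00331). RNA gene windows of 0 and 500 bp gave 0.204% and 0.613% at microRNA genes, and at 0 bp snoRNA genes kept 0.307% and small nuclear RNA genes 0.920%. K-mer lengths of 5 and 7 gave 242 and 1079 enriched k-mers, out of other totals. Except where the construction shows it, the cause was not tested. No paired analysis was possible because there was 1 group. Depth was unknown, so what it limits could not be set.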

Other observations

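The tests in this part were all chosen after the peaks at tRNA genes had been seen, except that of the X chromosome, which was set before its result was seen.

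RNA polymerase III genes other than tRNA genes also carried peaks. Of the 22 U6 genes, copied by that polymerase, 8 had a listed peak (36.4%), against 6 of 107 other small nuclear RNA genes (5.61%; odds ratio 9.62, 95% interval 2.91 to 31.8, Fisher's exact p = 0.000325). The other 6 included sls-2.1, sls-2.4, sls-2.9 and sls-2.15, genes for the SL2 spliced leader RNA, of which the peak counted for sls-2.9 had its summit in the tRNA gene M01E5.t1. A listed peak of signal 332 lay at rpr-1 and another of 187 (summit at II, 7200272) at mrpr-1, the gene for the RNA of RNase MRP. Of 20 nuclear rRNA genes none had a listed peak, and most had no ranked peak. Still, 2 of the 5S repeats, ZK218.20 and Y102A5D.10 on V, had peaks past the IDR threshold (signal 156 and 142) among those left out of the conservative set. Of 209 pseudogenic tRNA genes, 8 had a listed peak (3.83%; 1.95 to 7.37), the strongest at C52E12.t1 in an intron of unc-104 (222).

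The share of tRNA genes with a peak ranged widely between isotypes, and 1 isotype passed the threshold. Among genes of an assigned isotype with at least 2 genes, those for histidine tRNA had the lowest share, 5 of 20 (25%; 11.2 to 46.9), which was lower than among the other nuclear tRNA genes (odds ratio 0.223, adjusted exact p = 0.04997 over 22 groups, at the limit of the threshold), while 0 of 5 genes without an assigned isotype had a peak. Leucine genes (29 of 39, 74.4%) and aspartate genes (20 of 27, 74.1%) had the highest shares, with adjusted p-values of 0.326 and 0.412. The shares on X (163 of 276 genes, 59.1%) and on the autosomes (197 of 336, 58.6%) were close.

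A candidate explanation for the larger share of listed peaks on X is the density of tRNA genes there, since 45.1% of the nuclear tRNA genes lie on X. Without the peaks at tRNA genes the odds ratio fell from 1.33 to 0.524 (95% interval 0.404 to 0.678), which ended the excess. The interval passed below 1 where the test had foreseen that it would include 1, so the density of tRNA genes leaves the deficit among the remaining peaks unexplained, and its cause was not tested.

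Some listed peaks with no annotated gene of these kinds may mark further sites with tRNA-like promoter elements. Among 581 listed peaks away from tRNA, pseudogenic tRNA, snoRNA and small nuclear RNA genes, 21.5% had an A or B box within 100 bp of the summit, against 6.54% of their flanks (odds ratio 3.92, 95% interval 2.89 to 5.32, Fisher's exact p = 7.43e-19). Both boxes were present at 29 of these peaks. The strongest of them lay on III at 1601501 to 1601764 (signal 180, intergenic), with 2 more in introns of sms-3 nearby (150 and 144), and at 2031249 to 2031512 on III (169, intergenic, nearest TSS ckr-2). The flanks differed from the summits in base composition: away from tRNA genes AAAAAT occurred at 19.5% of 646 summits and in 46.7% of flanks. No control matched for composition was used for the boxes, so the excess cannot be told apart from an effect of composition. Boxes near the summit do not show that a site is transcribed, and expression was not measured here. Of all 978 listed peaks 129 (13.2%) were mostly repeated sequence, and the share among these 581 peaks is not given here.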
